A study of Saccharum spontaneum and Saccharum hybrid cultivar and Saccharum hybrid cultivar RB867515 with 14 samples.

How the data were processed

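Small RNA and PARE (degradome) libraries were made from Trizol-extracted total RNA of young leaves of 7 sugarcane genotypes and sequenced on an Illumina GAII, per the labels. For each of the 14 libraries the authors deposited a list of distinct tags with their counts, each tag listed once and not normalized. The tools for adapter trimming and read filtering, and any genome build, are not given in the sources used here. Small RNA tags ran from 18 nt to 31 or 34 nt and PARE tags from 18 to 20 nt. No reference genome was used, so tags were read by their sequence. The labels give 1 library per genotype and assay, and nothing says whether leaves of several plants were pooled.

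Genotypes were the units, grouped as species (S. spontaneum, S. officinarum, S. robustum) or hybrids (S. sinense, S. barberi, RB867515, SP70-1143), since each has 1 library. The classes, the tests, the sequence lists, the rule for named families and most alternative settings were fixed before the data were examined. The design had 7 small RNA units. It changed to 6 because the S. officinarum and S. robustum files were judged to hold 1 library, from the chi-square per tag of tags with a summed count of at least 500. Their counts were averaged, and the fit with 7 units is an alternative.

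A family count was the reads of 20 to 22 nt whose first 18 nt matched a listed mature sequence with at most 1 mismatch. RPM, the normalised read count, refers to the library's reads of 18 to 26 nt. The list held 48 entries in groups for development, small RNA machinery, nutrient and stress, grass lineage, triggers of phased siRNAs in anthers (another tissue), star strands, 5' tRNA fragments (RNA breakdown), and Arabidopsis and animal controls (background). Entries with at least 1 RPM in at least 3 units were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on the deposited counts, with library totals as offsets and Benjamini-Hochberg adjusted p under 0.05. Tags of 20 to 24 nt with at least 5 RPM in at least 3 units were tested the same way with TMM factors. The size classes were compared with an exact two-sided permutation test. Binomial intervals are exact (Clopper-Pearson, 95%).

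A hybrid lay outside the parental range when a family was at least 2-fold over the higher or under the lower of the S. officinarum and S. spontaneum files, among families at 10 RPM or more in at least 1 of the 3 libraries. For tag sharing, libraries were thinned at random to 1 number of reads per length, and hybrid tags with at least 2 reads were looked up in both parents. For cleavage, the 10 bases paired to microRNA positions 1 to 10 were searched at the start of PARE tags (position 0) and at positions 1 to 10 within them. The forms of these 10 bases listed for a family included some that do not pair fully, and all were pooled. The fully pairing forms alone were an alternative, whose count is not given here. A family was cleaved with at least 10 reads at position 0 and at least 5 times the mean of the others, with up to 200 permutations of each 10-mer and 8 control microRNAs as background. Position 0 reads of cleaved families were tested with edgeR as above, with library totals as offsets.

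Families named in the text are those past the test (at most 15), the 10 with the highest mean RPM, those outside the parental range in all 4 hybrids, and the 10 with the most PARE reads at the cut. Means were taken over the 6 units where the rule was written for 7 libraries. At most 2 tags in each direction are printed by sequence. Background on targets, parentage and ribosomal RNA is textbook knowledge.

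The tests were tested on simulated counts drawn from the real means, library sizes and dispersions. For the 30 families, 29.2% of 4-fold and 93.3% of 16-fold changes were recovered and 6.37% of calls were false. For the 7199 tags with 200 changed, 0% of 4-fold, 30% of 16-fold and 62% of 64-fold changes were recovered, and with 2000 changed 16.8%, 70.6% and 84.4%. For the 11 PARE families, 86.7% of 4-fold and 100% of 16-fold changes were recovered and 9.68% of calls were false. The biological coefficient of variation was 0.698 for families, 0.899 for tags and 0.418 for PARE.

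Alternatives covered scaling (TMM, library totals, DESeq2), abundance filters, mismatches, tag lengths, each genotype left out, the class of S. sinense and S. barberi, the parent used, thresholds, thinning and the cleavage background. The planned correlation of microRNA level and cleavage over genotypes was not made, for the reason given with the results. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.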

Results

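Small RNAs and the 5' ends of uncapped, cleaved RNA were sequenced from young leaves of mature plants of 7 sugarcane genotypes, with 1 library per genotype for each assay and 14 libraries in all. The second assay, called PARE or degradome sequencing, reads a short tag from the cut end of each RNA, so that a transcript sliced by a microRNA leaves tags that begin at the cut. The series asked how small RNAs differ between wild species and cultivated sugarcane that arose through hybridization. The species class held S. spontaneum, S. officinarum and S. robustum, and the hybrid class held S. sinense, S. barberi and the cultivars RB867515 and SP70-1143. The labels call only the 2 cultivars hybrids, and S. sinense and S. barberi were placed with them from textbook knowledge of their origin, before the data were examined.

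The small RNA libraries held 35209452 reads in S. spontaneum, 118140441 in the S. officinarum file, 83551228 in the S. robustum file, 37663167 in RB867515, 30970374 in S. sinense, 34060741 in S. barberi and 9232053 in SP70-1143. The PARE libraries held 7708034 reads in S. spontaneum, 10690766 in S. officinarum, 8610753 in S. robustum, 16254481 in RB867515, 40751904 in S. sinense, 11785266 in S. barberi and 34732781 in SP70-1143. In the counts of abundant tags, the small RNA files of S. officinarum and S. robustum differed by little more than the sampling noise of reading 1 library in separate runs. Their median chi-square per tag was 0.738 over 30125 abundant tags, where counting noise alone gives 0.455 and every other pair of small RNA libraries gave 12.4 to 525. They were counted as 1 sample with their mean, called here the officinarum-robustum library, which left 2 species units against 4 hybrids for small RNAs. Which of its labels is right was not settled. The PARE libraries of these genotypes were distinct, with a median chi-square of 52.3, and all 7 were used. Each genotype had 1 library, so p-values measure only the spread between genotypes, and intervals cover counting error only.

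The 24-nt siRNAs, the class that guides DNA methylation at transposons and repeats, were the most abundant length in all 7 small RNA libraries, and hybrids and species overlapped in their share. Among reads of 18 to 26 nt, 24-nt reads made up 33.1% ± 7.17 (SD, n = 4) in the hybrids, and 25.1% in S. spontaneum and 32.8% in the officinarum-robustum library. The share ran from 23.5% in S. sinense to 38.9% in S. barberi, so the hybrids alone spanned the species values. The 21-nt reads, the usual length of microRNAs, made up 21.9% ± 2.79 (SD, n = 4) in the hybrids against 23.6% and 26.5% in the species units. The 22-nt reads made up 10.8% ± 2.09 (SD, n = 4) against 8.72% and 11.95%. In an exact two-sided permutation test over the 15 splits, p was 0.667 for 24 nt, 0.2 for 21 nt and 0.867 for 22 nt, and the smallest p this design allows is 0.0667. A difference in size classes was therefore not detectable with these units.

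**Figure D1:**
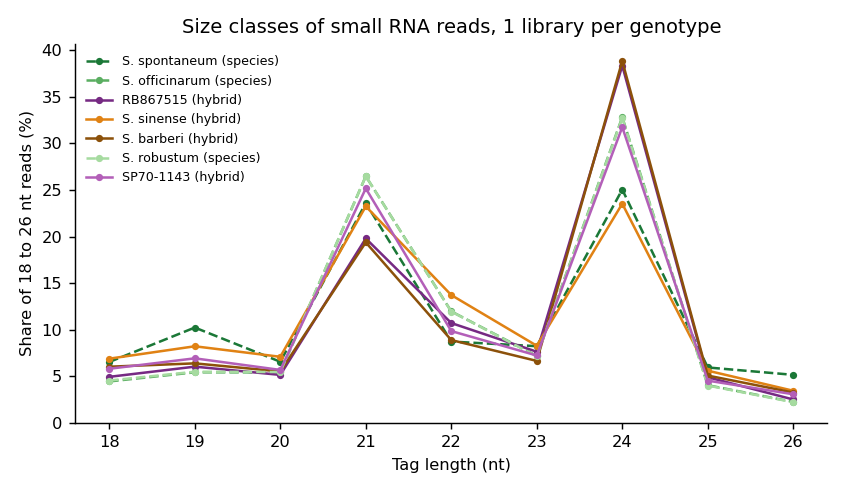
Percent of reads at each length from 18 to 26 nt (horizontal axis, nt) in each of the 7 small RNA libraries, 1 line per library, coloured by class. The 24-nt share lies between 23.5% in S. sinense and 38.9% in S. barberi, and the lines of the S. officinarum and S. robustum files lie on top of each other.

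The microRNA family with the highest mean over the 6 units was miR166, which restrains class III HD-ZIP factors of leaf polarity, at a mean of 26437 RPM, the normalised read count relative to all reads of 18 to 26 nt. It was followed by miR168, which targets the slicer gene ARGONAUTE1, at 23178, or 9193 without SP70-1143. In RB867515 and SP70-1143 miR168, at 24235 and 93101 RPM, lay above miR166, at 10232 and 11531. Next came miR156 at 2321, the growth-regulating factor repressor miR396 at 2171, the star strand of miR168 at 1678 and the GAMYB regulator miR159 at 1664. The auxin response factor regulator miR167 stood at 596, the phosphate-starvation microRNA miR399 at 536, the DICER-LIKE1 regulator miR162 at 484 and 5' fragments of tRNA-Arg at 444 RPM.

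Hybrids carried far more miR156, the microRNA that represses SPL transcription factors and keeps shoots juvenile, than the species. Its level was 688 RPM in RB867515, 1762 in SP70-1143, 5009 in S. barberi and 6397 in S. sinense, against 53.1 in S. spontaneum and 17.1 in the officinarum-robustum library. These levels cover tags that start as the listed sequence, and a form with an additional U at its 5' end, not counted in them, was the more abundant, at 308 RPM in S. spontaneum, 46.8 and 52.1 in the S. robustum and S. officinarum files and 1363 to 12247 in the hybrids. The fold of miR156 was 98.7 as listed and 35.6 with shifted starts counted. In the opposite direction, miR172, which acts against AP2-like repressors and marks the adult phase, fell from 16.2 and 20.2 RPM in the species units to 3.13 ± 2.51 (SD, n = 4) in the hybrids. The phosphate-starvation microRNA miR399 rose to 786 ± 502 (SD, n = 4) from 6.64 and 66.3, and miR444, a family of grasses that targets MADS-box genes, fell to 31.7 ± 17.7 (SD, n = 4) from 211 and 123.

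Of 40 listed families and fragments, 30 passed the abundance filter, and 10 differed between hybrids and species, 6 higher and 4 lower. The filter asks for 3 units and the species class has 2. An entry found only in hybrids can therefore pass and one found only in species cannot, so the 6 and the 4 are not on an equal footing. These came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 15 had an unadjusted p under 0.05. Of the 14 tested development families, 3 rose, 2 fell and 9 did not pass, with the same counts when adjusted over the list alone. In this list miR156 rose by 6.62 ± 1.36 on the log2 scale (SE, adjusted p = 0.0154). The auxin response factor regulator miR160 rose by 2.77 ± 0.77 (adjusted p = 0.0317), and tasiARF, a trans-acting siRNA that also restrains auxin response factors, rose by 2.45 ± 0.70 (adjusted p = 0.0317). At 0.302 and 0.369 RPM in the species units, tasiARF passed the filter of 1 RPM through the hybrids alone. In the hybrids miR172 changed by -2.54 ± 0.82 and miR167 by -1.71 ± 0.55 (adjusted p = 0.0422 for each). The 9 others included miR166 at -1.27 (adjusted p = 0.161), miR159 at -0.98 and miR396 at -0.62.

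Of the 6 tested nutrient and stress families, 2 rose and 4 did not pass over all families, and 4 rose when adjusted over the list alone. The phosphate-starvation family miR399 rose by 4.43 ± 1.26 (adjusted p = 0.0317), and miR169, which targets NF-YA factors and responds to nitrogen and drought, rose by 3.31 ± 0.98 (adjusted p = 0.0328). The additional calls over the list alone, named after their values were seen, were the SPX-domain transporter regulator miR827 at 3.01 and the monocot family miR528 at 2.82, both with an adjusted p of 0.0370 over the list alone and 0.0617 over all families. The 1 tested family of the grass lineage, miR444, changed by -2.39 ± 0.68 (adjusted p = 0.0317). Neither of the 2 small RNA machinery families passed, with miR168 at 3.15 (adjusted p = 0.0867) and miR162 at 1.13 (adjusted p = 0.226). The mean miR168 level of 32916 ± 40971 RPM (SD, n = 4) in the hybrids rested on 93101 in SP70-1143. Neither of the 2 tested star strands passed, with that of miR168 at 2.14 (adjusted p = 0.0865) and that of miR156 at 1.55 ± 1.15 (adjusted p = 0.318). The star strand of miR156 thus did not show the rise of 6.62 seen for miR156. It lay above both species units in 3 of 4 hybrids, but not in RB867515, at 20.7 RPM.

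Among 5' tRNA fragments, which form when tRNAs are cut or broken down, 1 of 5 rose, 1 fell and 3 did not pass, with the same counts over the list alone. Fragments of tRNA-Asp (tRF-Asp) changed by -4.42 ± 0.59 (adjusted p = 0.00145), from 24.2 RPM over the species units to 1.13 ± 0.23 (SD, n = 4). Fragments of tRNA-Arg (tRF-Arg) rose by 3.41 ± 0.83 (adjusted p = 0.0291), although with tags of 18 to 24 nt the change was 0.16. Of the microRNAs that trigger phased siRNAs in anthers, miR2275 had 0 reads and miR2118 at most 4.57 RPM, in S. barberi, whose highest control was at 0.274. Control sequences of Arabidopsis reached at most 0.0603 RPM in any library and animal controls 4.36. Not above the highest control of their own library were tasiARF in both species units and 1 hybrid (hybrid mean 1.83 ± 0.70, SD, n = 4), miR169 in both species units, tRF-Asp in 2 hybrids and miR172 in SP70-1143, so their folds rest partly on values at background. The same held for the calls over the list alone, miR827 in both species units and RB867515, and miR528 in both species units and SP70-1143.

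All 4 hybrids lay above both species units for 13 of the 30 entries and below both for 7, or 66.7% of entries where chance gives 13.3% for a single entry. The entries come from the same 6 units and are not independent, so this share is not a test. The filter also admits entries found only in hybrids and none found only in species, so the 13 and the 7 cannot be weighed against each other. Among files whose reads end at 34 nt, the S. officinarum file and the 4 hybrids, miR156 in the hybrids was 38.9-fold to 362-fold above that file. Tags that differed from an abundant tag only at position 12 still parted the classes, at 2.01% to 14.4% of the abundant tags' reads in the species files and 0.285% to 0.673% in the hybrids. Position 10 parted them as well, at 0.0501% to 0.0928% in the species files and 0.104% to 0.184% in the hybrids. Position 2 did not part them, with the S. officinarum file at 1.27%, the other species files at 0.140% and 0.252% and the hybrids at 0.653% to 1.11%, so whether the run follows the class stays open for small RNAs. With TMM scaling, which moved the median fold change by -1.11, 1 family was higher (miR156) and 7 were lower, and with DESeq2, which moved it by -0.70, 9 were higher and 6 lower. The calls depended on which unit was left out, with 7 entries called without RB867515, 11 without S. sinense and 10 without SP70-1143. Without S. spontaneum only tRF-Asp passed, without S. barberi only tRF-Asp and miR156, and without the officinarum-robustum library 3 entries passed, among them miR399 and tRF-Asp. With starts shifted by up to 2 nt also counted, edgeR called 0 entries, 15 had an unadjusted p under 0.05, and miR156 stood at 5.15 ± 1.36 (adjusted p = 0.0542, and 4.09e-09 to 0.843 over all alternatives). With S. sinense and S. barberi counted as species, edgeR called 0 entries and 5 had an unadjusted p under 0.05.

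**Figure D2:**
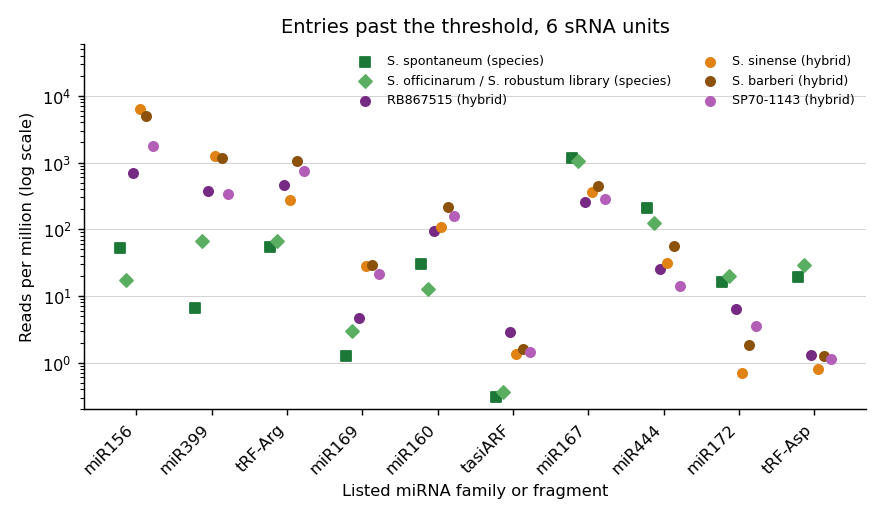
RPM (relative to reads of 18 to 26 nt, log axis) of the listed families past the test in each of the 6 units, with the species units as squares and diamonds and the hybrids as circles. For miR156 the 4 hybrids lie between 688 and 6397 and the species units at 53.1 and 17.1.

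Single tags were compared without a genome, so most of them have no name. Among 7199 abundant tags of 20 to 24 nt, 1028 were higher and 1068 lower in hybrids than in species, and 3498 had an unadjusted p under 0.05 (edgeR with TMM). Here too the filter of 3 units lets tags found only in hybrids pass, but not tags found only in species. Called tags were found at every length, from 21.9% of the 21-nt tags to 33.6% of the 24-nt and 37.0% of the 23-nt tags. This order did not hold with DESeq2, which called 55.2% of the 21-nt and 52.1% of the 24-nt tags. The tags named here, among those with the lowest adjusted p in each direction, were 4 pieces of ribosomal RNA, recognised from textbook sequence. CGACUCUCGGCAACGGAUAU, of 5.8S rRNA, rose by 3.99 ± 0.30 on the log2 scale, and GUUAACGAACGAGACCUCAG, of 18S rRNA, rose by 4.13 ± 0.32. GAAGACCCUGUUGAGCUUGACUCU, of 25S rRNA, changed by -3.97 ± 0.25, and the 22-nt tag GCCGGCGAUGCGCUCCUGGCCU, of 18S rRNA, by -8.48 ± 0.50, from 1152 and 2121 RPM in the species units to 6.21 to 10.97 in the hybrids. Each had an edgeR adjusted p of 0.00725 and the same direction in 4 of 4 hybrids. The risen tags stood at 0.573 to 1.27 RPM in the species units, so they passed the filter of 5 RPM through the hybrids alone. With library totals in place of TMM, which moved the median by 1.01, 2057 tags were higher and 461 lower. With S. sinense and S. barberi left out, edgeR called 0 tags and 1017 had an unadjusted p under 0.05, and without S. spontaneum 1364 tags were called.

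Hybrid leaves were then set against both parental species, taken from textbook knowledge as S. officinarum and S. spontaneum, to see whether microRNA levels lay between those of the parents. They often did not. Above the higher parent by at least 2-fold in all 4 hybrids were miR156, the auxin response factor regulator miR160, the phosphate-starvation family miR399 and tRF-Arg. Below the lower parent by at least 2-fold in all 4 hybrids were miR167, miR172, miR444 and tRF-Asp. For miR160 the hybrids held 93.6 to 216 RPM against 29.8 in S. spontaneum and 12.9 in the S. officinarum file, and for miR167 they held 254.7 to 450.4 against 1154 in S. spontaneum and 1080 in the S. officinarum file.

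Over the 4 hybrids, 101 comparisons of a family with both parents gave 32 above, 22 below and 47 within the parental range. RB867515 had 8 above and 7 below, S. sinense 8 and 4, S. barberi 9 and 4, and SP70-1143 7 and 7. The officinarum parent was the S. officinarum file as labelled, and if its library came from S. robustum the values compare the hybrids with that species. TMM scaling gave 22 above and 39 below, with 1 family above and 7 below in all 4 hybrids. These are values of single libraries with no test.

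SiRNA sequences of the hybrids matched the S. officinarum file more often than S. spontaneum. After all libraries were thinned to 2808666 reads of 24 nt, 15.4% ± 2.05 (SD, n = 4) of the hybrids' 24-nt tags with at least 2 reads were found only in the S. officinarum file and 6.13% ± 0.39 only in S. spontaneum. Another 11.5% were found in both and 66.9% in neither, a share that was 87.1% over all tags and 36.6% over tags with at least 5 reads. The ratio of the exclusive shares was 2.54 ± 0.47 (SD, n = 4), from 2.07 in S. sinense to 3.02 in RB867515. In RB867515, 17.9% of tags (exact binomial 95% interval 17.8% to 18.1%) were found only in the S. officinarum file. The ratio was 2.38 for 21-nt and 2.27 for 22-nt tags.

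PARE tags went the other way. Of the hybrids' 20-nt PARE tags with at least 2 reads, 11.4% ± 0.57 (SD, n = 4) were found only in S. officinarum and 16.8% ± 0.34 only in S. spontaneum, a ratio of 0.678 ± 0.038. That ratio was 0.810 over all tags and 0.437 over tags with at least 5 reads. The thinned parents still differed in distinct tags, with 1670166 of 24 nt in the S. officinarum file and 1560757 in S. spontaneum, and 2622760 and 2729843 for PARE. No test was made of either ratio, and which genotype the officinarum-robustum library came from stays open.

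**Figure D3:**
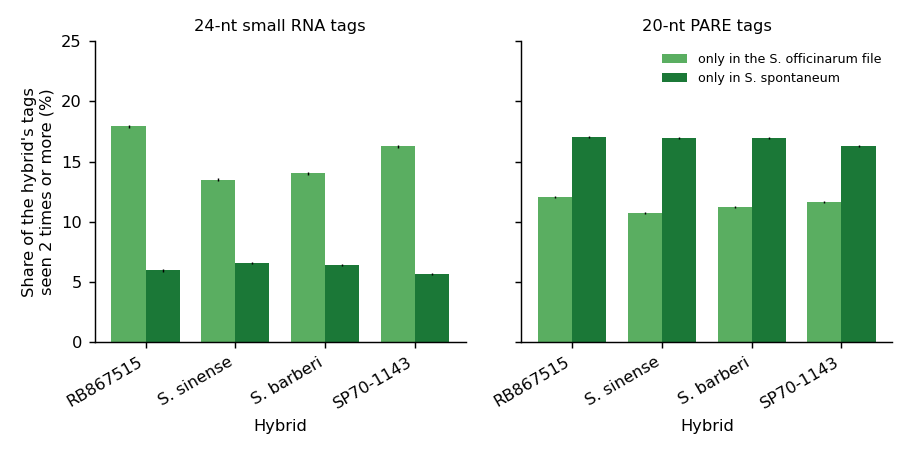
Percent of the tags of each of the 4 hybrids that were found only in the S. officinarum library or only in S. spontaneum, for 24-nt small RNA tags and 20-nt PARE tags at equal numbers of reads per length, with exact binomial 95% intervals as error bars. The S. officinarum share is the larger for small RNA (means 15.4% and 6.13%) and the smaller for PARE (means 11.4% and 16.8%).

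MicroRNA-guided slicing was visible in the PARE tags of every genotype. A transcript cut opposite microRNA positions 10 and 11 leaves tags that begin with the bases paired to positions 10 to 1, and such tags stood above the same bases met 1 to 10 nt further inside tags. The cut sites of miR160 (known targets: auxin response factors), miR164 (NAC factors), miR171 (SCL factors), miR172 (AP2-like factors) and miR396 (growth-regulating factors) were found in all 7 libraries. Those of miR169 (NF-YA factors) were found in 5 libraries, and those of miR156 (SPL factors) and miR394 (the LCR F-box gene) in 4 each. Those of miR168 (ARGONAUTE1) were found in 2, and those of miR166 (class III HD-ZIP factors) and miR397 (laccases) in 1 each.

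A family counted as cleaved with at least 10 reads at the cut and at least 5 times the mean of the next 10 positions, and 11 of 30 families met this in at least 1 library, with 6 to 8 per library. The ratio for miR160 ran from 23.1 in S. robustum to 2298 in RB867515. None of the 8 control microRNAs met it, their highest ratio being 2.12 where they had at least 10 reads at the cut, and 0.775% to 1.12% of permuted 10-mers did. With distinct tags in place of reads 3 families were cleaved, and against the highest of the 10 positions 7 were.

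**Figure D4:**
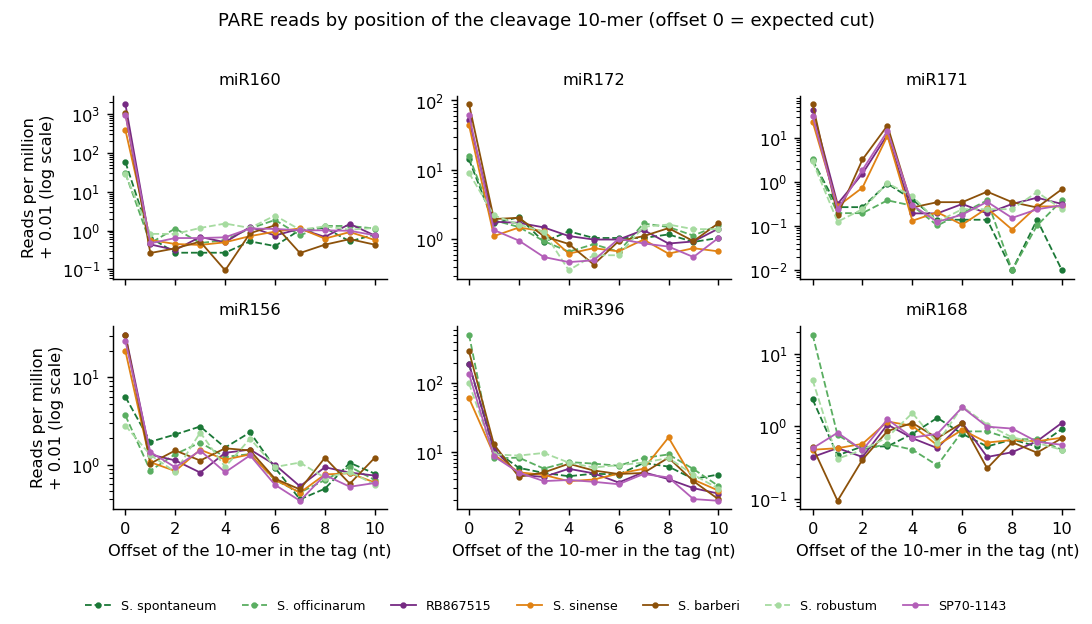
PARE RPM (reads relative to the library total, log axis, with the small constant on the axis added) by the position within the tag at which the bases paired to the microRNA begin (0 to 10), for 6 families and 7 libraries, species dashed and hybrids solid. Position 0 is the predicted cut, and for miR160 the hybrids reach 389 to 1810 RPM there against 28.7 to 58.4 in the species.

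Reads at cut sites differed between hybrids and species for most cleaved families. No transcriptome was used, so reads are counted at the 10 bases of the cut site, and the targets named are those known for each family. Reads at the miR160 cut site, known from auxin response factors, reached 1060 ± 583 RPM of the library total (SD, n = 4) in the hybrids against 39.0 ± 16.8 (SD, n = 3) in the species. Those at the miR156 site, known from SPL genes, rose to 26.8 ± 5.005 from 4.13 ± 1.65, those at the miR171 site (SCL genes) to 39.0 ± 15.1 from 3.10 ± 0.19, and those at the miR172 site (AP2-like genes) to 61.9 ± 19.2 from 12.9 ± 3.44 (SD, n = 4 and n = 3 in each). Reads at the miR168 cut 10-mer fell to 0.458 ± 0.062 from 8.26 ± 8.62, a species mean that is 3.32 without S. officinarum. Not above the highest control of their own library at the cut position were miR168 in the 4 hybrids and S. robustum, miR397 in all but S. spontaneum, miR394 in S. barberi, and miR156, miR166, miR171 and miR394 in S. robustum, where that control stood at 4.41 RPM.

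Of 11 cleaved families tested, 5 were higher and 2 lower (edgeR, Benjamini-Hochberg), each in 4 of 4 hybrids. The rule that let a family in used these same reads, in any 1 library. The lower families met it in few libraries, miR397 in 1 and miR168 in 2, so their difference from the other libraries is partly built in. With all 30 families that had any read at the cut tested, edgeR called 6 higher and 3 lower, among them these 7. On the log2 scale miR160 rose by 4.77 ± 0.61 (adjusted p = 0.000126), miR171 by 3.65 ± 0.42 (adjusted p = 9.77e-05), miR156 by 2.70 ± 0.38 (adjusted p = 0.00017) and miR172 by 2.26 ± 0.37 (adjusted p = 0.000377). Reads at the site of miR169 rose by 1.12 ± 0.30 (adjusted p = 0.00675), a direction that flipped to -0.10 with TMM and -0.040 with DESeq2. This call rested on the tag TTCTTGGCTTTCACGTTCCA, with 71.6% to 90.3% of its reads in every library, and without it the change was 0.11 ± 0.44 (adjusted p = 0.871). The reads of miR168 changed by -4.16 ± 0.67 (adjusted p = 0.000377), and those of the laccase family miR397 by -3.11 ± 0.77 (adjusted p = 0.00517) on 27 reads in all. For miR168 the tag CACCAAGCGACGCTACTGGA, whose transcript was not identified, made up 91.2% of the S. officinarum reads and was the most abundant in each species library. Without the most abundant tag of each library, which was another tag in the hybrids, the change was -1.64 ± 0.54 (adjusted p = 0.00814). Not past the threshold were miR164 at 0.74, miR166 at 0.62, miR394 at -0.34 and miR396 at -0.65.

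The PARE libraries of the classes also differed in a substitution signature, which may come from the sequencing run. Tags that differed from an abundant tag only at position 2 had 1.92% to 2.19% of the reads of those abundant tags in the hybrids and 0.204% to 0.282% in the species. Position 10 parted the classes too (0.872% to 1.66% in the hybrids and 0.260% to 0.294% in the species). Position 12 did not (0.281% to 0.387% and 0.352% to 0.360%). The sequencing run and the class therefore cannot be told apart. TMM, which moved the median by -1.18, gave 3 higher and 4 lower, and DESeq2, which moved it by -1.22, gave 4 and 4. Taken relative to the reads at positions 1 to 10, the rise of miR171 was 1.07, against a background that held another miR171 peak at position 3 (11.1 to 18.9 RPM in the hybrids and 0.374 to 0.929 in the species). With S. sinense and S. barberi counted as species, edgeR called 0 families and 0 had an unadjusted p under 0.05.

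The question of whether a microRNA and the slicing it guides moved together had different answers for different families. Both the level of miR156 and the reads at its cut site rose in hybrids, as did those of miR160. For miR396 both values were negative (-0.62 for the microRNA and -0.65 for the cut), neither past its test. They were opposed for the AP2-like regulator miR172, whose level fell while its cut reads rose (-2.54 and 2.26), and for the ARGONAUTE1 regulator miR168 (3.15, not past its test, and -4.16). These 5 families kept their relation with TMM and DESeq2, while miR164, miR166, miR169, miR171 and miR394 did not keep it under every scaling. For miR396 the cut change was 0.065 ± 0.40 (SE) without the most abundant tag of each library. The miR168 cut reads were not above the controls in any hybrid, so its relation rests partly on values at background. In all, 6 of the 10 families tested in both assays had the same sign, and 5 did with TMM. No correlation over genotypes is given, because the PARE libraries fell into separate clusters by class. Hybrids shared 57.1% to 65.6% of PARE tags with each other and 33.8% to 43.6% across classes, and neither cluster held 6 genotypes.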

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

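All the tests of explanations in this part were chosen after the results had been seen. The level of tasiARF stood at 2.86 RPM in RB867515 against 1.36 to 1.61 in the other hybrids, far from them for a group of 4 (gap over range 0.831). Chance singles out about 1 in 20 such groups, and 1 of 30 was singled out.

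The small RNA files labelled S. officinarum and S. robustum resembled each other far more than any other pair in the counts of abundant tags. Shared tags set them apart less. At equal reads 61.5% and 62.7% of their 24-nt tags were found in the other file (65.0% and 65.2% between draws of the same file), and 57.4% and 53.3% for RB867515 and SP70-1143. At 21 nt 65.8% of the SP70-1143 tags were found in RB867515 and 62.7% of the S. robustum tags in S. officinarum. There 74.3% of the S. officinarum tags were found in S. robustum, while draws of the same file shared 79.1% in S. officinarum and 78.9% in S. robustum. Whether similar leaves of related genotypes explain this was not decided by their PARE libraries. These differed with a median chi-square per tag of 52.3, but 67.4% of their tags lay within 2-fold. The S. sinense and S. robustum PARE libraries gave 4.58 with 27.7% of tags within 2-fold, so this chi-square does not rank likeness. Sharing at 21 nt was lower than between draws of the same file. In abundant tags the small RNA files differed by 0.738, little above counting noise, as would 1 library read in separate runs. Which genotype it came from stays open, and a wrong label of either file was not tested further.

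In hybrids miR156 was higher and miR172 lower. Another start position of miR156 in the species was argued against as the whole cause, since the log2 change with shifted starts counted was 5.15 ± 1.36, although no longer past the threshold (edgeR adjusted p = 0.0542, and 4.09e-09 to 0.843 over all alternatives). Whether the sequencing run follows the class stays open. Tags 1 substitution from an abundant tag at position 12 had at least 2.01% of its reads in the species files and at most 0.673% in the hybrids, and position 10 also parted the classes. Position 2 instead put the S. officinarum file (1.27%) with the hybrids (0.653% to 1.11%), and the S. officinarum and S. robustum files differed 1.08-fold in miR156. Library preparation cannot be told apart from class, since the labels give 0 batches that are known to hold both. A difference in leaf developmental phase may underlie the pattern. It was predicted to lower the reads at miR172 cut sites along with miR172, but these reads were higher in hybrids by 2.26 ± 0.37 on the log2 scale. Cut reads also depend on the level of the target transcripts, which was not measured, and the PARE run may follow the class. The leaf phase therefore stays open, as does the genotype itself.

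Relative to library totals, reads at cut sites were mostly higher in hybrids (5 families higher and 2 lower, and 3 and 4 with TMM). Of 35 splits of the 7 PARE libraries, 1, the real one, gave 7 families past the threshold and the highest other gave 0. A random grouping is argued against but not excluded, since 1 in 35 is the smallest share these splits allow. More random decay in the species libraries would dilute all families alike and is argued against as the whole cause, since of the 5 families above the controls in both classes miR160 and miR396 differed by 5.42 ± 0.87 (SE) in their log2 change. Whether a single transcript per family is the cause was only partly tested, by taking out the most abundant tag of each family in each library. After that 5 families passed, miR156, miR160, miR168, miR171 and miR172. For each of these that tag was not the same in every library, so different tags could be taken out in the classes. For miR160 it was the same in all libraries but S. robustum, and the change of 3.82 ± 0.47 without it argues against a single tag there. Without the most abundant tag, miR169 (0.11 ± 0.44) and miR397 (-2.07 ± 0.92) did not pass and miR168 went from -4.16 to -1.64. The sequencing run cannot be told apart from class, with tags 1 substitution from an abundant tag at position 2 at 1.92% of its reads in the lowest hybrid and 0.282% in the highest species, and a true difference in slicing between the classes stays open and untested. For the 6 small RNA units the 15 splits are too few for a share under 0.05, with 10 families and 2096 tags in the real split and 0 in the highest other for each.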

How the results depend on the processing

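Alternatives chosen after the data were seen were the counts with 7 units or with 1 file of the shared library, shifted starts, near-identical tags left out, the mean parent, the S. robustum file for sharing, PARE relative to positions 1 to 10 and PARE without top tags. Of 82 alternative values of the main comparisons, 64 stayed the same and 18 moved, and of 349 for single families and tags, 255 stayed, 89 lost their call with the same direction and 5 reversed. Against 10 entries called in the main fit, edgeR called 2 without a filter (38 tested) and 5 with 18 to 24 nt. It called 0 with S. sinense and S. barberi counted as species (5 at an unadjusted p under 0.05) and 0 with shifted starts (15 unadjusted). Leaving out 1 genotype gave 1 to 11. Against 2096 tags called in the main fit, DESeq2 called 3885, a minimum of 2 RPM gave 4404 and of 10 gave 1046 (more and fewer tags tested), and 7 units gave 4875. Without S. sinense and S. barberi edgeR called 0 tags (1017 unadjusted) and with them as species 0 (289 unadjusted). Leaving out 1 genotype gave 1364 to 2341. PARE calls fell from 7 to 0 with these genotypes as species (0 unadjusted), and ranged from 7 to 8 with 1 genotype left out. A minimum of 50 RPM left 35 of 54 cases outside the parental range, with fewer cases compared. Cleaved families numbered 3 by distinct tags and 7 against the highest position. With S. sinense and S. barberi as species, the small RNA changes reversed for miR156 (-1.23), miR169 (-0.24) and miR399 (-0.83), and the PARE change of miR169 reversed with TMM (-0.10) and DESeq2 (-0.040). Where no construction is given, the cause was not tested. The 24-nt difference of 4.20 points ran from 0.335 to 8.07 with 1 genotype left out. With 1 species unit left, that unit is assumed to vary like the hybrids. The alternatives foreseen for the correlation (pseudocounts of 0.1 and 5, no mismatch) were not run, since no correlation was made. No paired analysis was possible because each genotype has 1 library and every replicate is number 1. Depth limits the least abundant entries, such as miR397 with 27 PARE reads in all.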

Other observations

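The form of miR156 differed along with its level. The 20-nt form UGACAGAAGAGAGUGAGCAC made up 4.60% to 9.59% of the reads of both listed forms in the species files and 27.5% to 44.3% in the hybrids. The rest began with an additional U (UUGACAGAAGAGAGUGAGCAC), which was at 46.8 to 308 RPM in the species files and 1363 to 12247 in the hybrids. The usual first bases of each size class were seen, with A at the start of 50.8% to 57.6% of 24-nt reads and U at the start of 48.8% to 65.0% of 21-nt reads.

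PARE tags at the miR171 sites showed another peak. Tags that begin 3 nt upstream of the predicted cut stood at 11.1 to 18.9 RPM in the hybrids, where the median of the other positions was 0.230 to 0.339, and at 0.374 to 0.929 in the species, where it was 0.130 to 0.232. The tag counts at this position were 191 to 492 in the hybrids and 4 to 8 in the species. This was noticed in the values and not tested, and the PARE run follows the class here as well.

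Over the 6 units, the order of miR172 was the exact reverse of that of miR156, within the species as well as within the hybrids. From the lowest to the highest miR156, the officinarum-robustum library, S. spontaneum, RB867515, SP70-1143, S. barberi and S. sinense held 17.1, 53.1, 688, 1762, 5009 and 6397 RPM of miR156. In the same order they held 20.2, 16.2, 6.48, 3.505, 1.86 and 0.697 RPM of miR172. Of the 29 other entries tested, 1, miR172, was in exactly reversed order. The miR172 value of SP70-1143 equals that of an animal control in the same library (3.505 RPM), so its place in the order rests on a value at background, while the other 3 hybrids lay above the controls of their own libraries. It was picked after the values were seen, and no correlation is given, because the units fall apart by class and neither class holds 6.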
